A study of Danio rerio with 20 samples.

How the data were processed

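Gene expression was measured by RNA sequencing of poly(A)-selected RNA from whole zebrafish embryos. Per the labels, each library came from a pool of about 50 embryos collected within a fertilization window of 15 min, with about 500 ng of RNA as input and paired reads of 150 bases. MPNP libraries held un-genotyped progeny of intercrosses of fish heterozygous for an mdm2 mutation and homozygous for mutations in puma, noxa and p21 (the pnp background), and PNP libraries held progeny of intercrosses in the pnp background alone. By Mendelian expectation about 25% of the embryos in an MPNP pool lacked mdm2, and others were heterozygous for the mutation. The actual shares were not measured. There were 20 libraries in 10 groups, with 2 libraries for each pool type at 8, 10, 12, 14 and 16 hours post fertilization (hpf).

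The deposited values were length-scaled transcript shares (TPM) for 32057 Ensembl gene IDs, rounded to 2 decimals by the authors, and each library had the same total. The submitters' processing notes name STAR 2.7.3a, RSEM 1.3.3, HTSeq 0.12.3, DESeq2 1.42.1, R 4.3.3 and the genome build GRCz11; which of them made the TPM table is not given in the sources used here. TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval is given. The table also held unnamed columns without values, which were not used. IDs were paired with symbols from a gene name table, which matched 28988 of the 32057 IDs and 14301 of the 14774 genes tested; symbols are given in lower case, and a symbol shared by several IDs is given with its ID. No annotation of GRCz11 was at hand, so no coordinates are given; an annotation of another assembly, GRCz12tu, was used only for the order of genes around mdm2.

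The values were analysed as log2(TPM + 1), so a fold change is on that scale and understates the change of low genes. Genes with a mean TPM of at least 1 over the 20 libraries were tested (14774 genes). limma 3.58.1 (R 4.3.3) was fitted to all 20 libraries with 1 mean per group, leaving 10 residual degrees of freedom, with empirical Bayes moderation and an intensity trend. Contrasts were MPNP minus PNP at each stage, the mean of these 5 differences, the 16 hpf difference minus the 8 hpf difference, an F test of whether the difference varied over the stages, and PNP at 16 hpf minus PNP at 8 hpf. P-values are 2-sided and were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05; "adjusted p" means this value throughout. Fold changes are given with standard errors (SE) and TPM means with standard deviations (SD). The labels do not say whether the libraries of a group came from separate crosses, so p-values measure only the spread between these samples.

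The tests, the genes to be named and 24 gene lists were fixed before the data were examined. The lists described here were the study title genes, p53 targets, apoptosis machinery, DNA repair and checkpoint, G1/S and replication, G2/M and mitosis, ribosome biogenesis, stress and immediate early genes, innate immunity, neural crest, neural progenitors, neurogenesis, somite and muscle, tailbud and notochord, endoderm, blood and endothelium, heart with kidney and lateral plate, epidermis, hatching gland, yolk syncytial layer, primordial germ cells, maternal transcripts and mitochondrially encoded genes. Of 691 list entries 647 matched a gene ID, 104 of them after a paralog letter was dropped, so a matched symbol can stand for either paralog. Lists with at least 5 measured members (23 lists) were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over lists within a contrast, with an estimated correlation per list and with fry (limma, statmod 1.5.0). Named were the engineered loci and the study title genes. The rule added, for the average, the 12 genes with the largest change in each direction among those called, with a mean TPM of at least 5 in the higher pool and the same sign at 5 stages. Per stage it added 6 in each direction whose libraries did not overlap, again with a mean TPM of at least 5, and for the stage difference the 10 with the smallest p. For each list described it added up to 4 with the smallest p, and for development the 6 with the largest change in each direction. Genes with clone-derived names were counted but not named.

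Same-numbered libraries deviated together. The correlation across genes of the deviations from the group means between MPNP and PNP libraries with the same replicate number was 0.485, 0.586, 0.615, 0.539 and 0.601 at the 5 stages, and 20 of 20 libraries had their best match outside their group in a library with their own number. The numbers were therefore taken to pair the samples; the pairing comes from the data, since the labels do not say what a number stands for. A fit with the replicate number within stage as a block (5 residual degrees of freedom), also chosen before the data were examined, called 579, 444, 204, 263 and 516 genes at the 5 stages. Its values are given beside the counts of genes called between the pools and beside the calls of the genes named and the lists described that it changed. For development the block over all stages is given.

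The other settings fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at a mean TPM of 5, median-ratio scaling, quantile normalization, moderation without a trend and with robust estimates, each single library left out, each stage fitted alone, and removal of a developmental offset, in which each library was moved along the stage slope of every gene by the offset that fitted it best. The fits were tested on simulated data with 200 of 14774 genes changed. In data with independent libraries, the single-stage comparison at 8 hpf recovered 54% of 2-fold and 94% of 4-fold changes, and the average over stages recovered 96% and 99%; false genes made up 8.07% and 7.14% of the calls, and the block lowered the recovery of 2-fold changes at 8 hpf to 36%. With a shared replicate effect, the block recovered 85% of 2-fold changes at 8 hpf, against 53% without it. In simulated data with this shared effect and no stage difference, the F test without the block called 0 genes. In this setting false genes were also rare without the block in the other comparisons, from 0% to 2.02% of the calls. The F test was not checked in this way on independent libraries or with the block, so the 0 is a limited check.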

Results

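The series followed transcript levels in zebrafish embryos between 8 and 16 hpf, to ask how the targets of p53 are induced when Mdm2, the ubiquitin ligase that holds p53 down, is missing from part of the embryos. MPNP pools, in which about 25% of embryos were expected to lack mdm2, were set against PNP pools of the same stage. Both pool types carried mutations in bbc3 (puma), pmaip1 (noxa) and cdkn1a (p21), which encode mediators of p53-driven cell death and arrest. There were 2 libraries per pool type and stage, 20 in all. Between 13080 and 15326 genes reached 1 TPM in a library, and the 10 most abundant genes took from 8.62% to 14.7% of the TPM.

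Stage accounted for most of the variation between libraries. The first principal component, which ordered the libraries by stage, took 70.0% of the variance. Replicate libraries of a group correlated across genes at Pearson's r from 0.973 to 0.982. The third component (7.8%) separated the libraries numbered 1 from those numbered 2 at every stage, and the fourth (2.6%) separated MPNP from PNP. Across all stages, 5962 genes were higher and 2090 lower in the libraries numbered 2 (limma, adjusted p under the 0.05 threshold). The elongation factor gene eef1a1l1 was the most abundant gene in the 10 libraries numbered 1, and ENSDARG00000080337, which has no symbol in the name table, in the libraries numbered 2 except PNP at 16 hpf. The 13 genes of the mitochondrially encoded list took from 1.14% to 3.35% of the TPM. Mitochondrial ribosomal RNA is not on that list and was not counted.

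**Figure D1:**
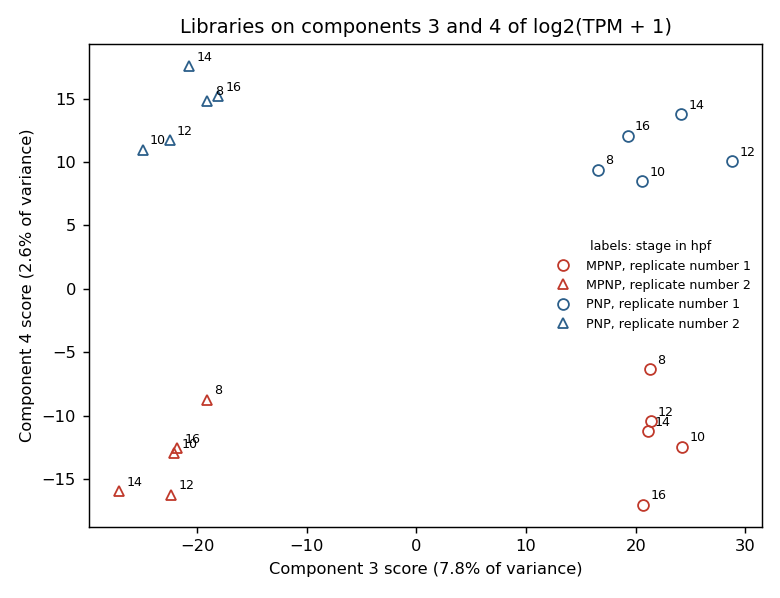
Scores of the 20 libraries on principal components 3 (x axis, 7.8% of the variance) and 4 (y axis, 2.6%) of log2(TPM + 1), in arbitrary units, each point 1 library labelled with its stage in hpf. Libraries numbered 1 (circles) and 2 (triangles) lie on opposite sides of component 3, and MPNP (red) and PNP (blue) on opposite sides of component 4, at each of the 5 stages.

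The engineered loci came first, as a check of the labels. The mdm2 transcript (ENSDARG00000033443) was at 133 ± 23 TPM in MPNP and 118 ± 8.8 TPM in PNP at 8 hpf (SD, n = 2), and at 321 ± 5.7 against 114 ± 0.89 TPM at 16 hpf. Its log2 difference between the pools was 0.16, 0.44 and 0.89 at 8, 10 and 12 hpf and 1.49 at 16 hpf. Averaged over stages it was higher in MPNP by 0.88 ± 0.11 (SE; limma adjusted p = 0.00023). TPM over a whole gene does not tell mutant from wild-type transcripts, so these values do not show the share of mdm2 mutants in a pool. The mutated p53 targets were transcribed in both pool types. bbc3 (ENSDARG00000069282) was higher in MPNP by 1.50 ± 0.16 on average and cdkn1a (ENSDARG00000076554) by 0.96 ± 0.10, with limma adjusted p of 7e-05 and 4.6e-05. pmaip1 (ENSDARG00000089307) differed by 0.59 ± 0.34, which did not pass (limma adjusted p = 0.45) except with the replicate block (0.0043). Its libraries numbered 2 lay above those numbered 1 in both pools.

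The genes of the study title had positive differences between MPNP and PNP at 5 of 5 stages, though not each difference passed at a single stage. foxo3b (ENSDARG00000042904), a forkhead transcription factor, differed most, by 1.46 at 8 hpf and by 2.72 at 16 hpf on the log2 scale, and by 2.18 ± 0.18 on average (limma adjusted p = 9.2e-06). ccng1 (ENSDARG00000076667), which encodes cyclin G1, was at 895 ± 4.8 against 790 ± 9.0 TPM at 8 hpf and at 1340.5 ± 136 against 545 ± 52 TPM at 16 hpf, and differed by 0.84 ± 0.12 on average (limma adjusted p = 0.00067). fbxw7 (ENSDARG00000060994), a substrate receptor of a ubiquitin ligase, was higher in MPNP by smaller amounts, with differences of 0.26, 0.21, 0.40, 0.78 and 0.60 and an average of 0.45 ± 0.11 (limma adjusted p = 0.031). The fourth title gene is cdkn1a. The study chose these genes, so their direction is not independent evidence.

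**Figure D2:**
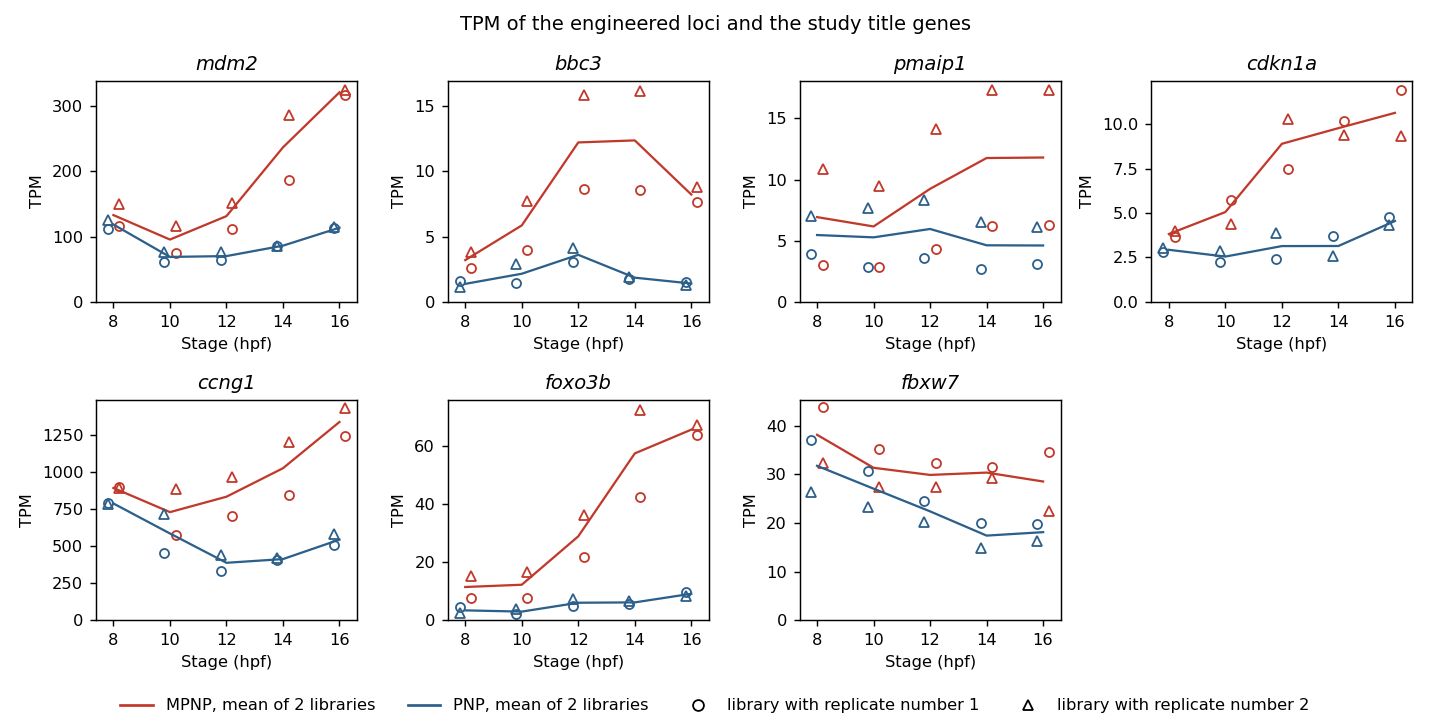
TPM (y axis, linear, from 0) against stage in hpf (x axis) for the engineered loci and the study title genes, with each library as a point (circles numbered 1, triangles numbered 2) and the mean of 2 libraries as a line, MPNP in red and PNP in blue. The mdm2 mean in MPNP reaches 321 TPM at 16 hpf against 114 TPM in PNP, and that of foxo3b 65.8 against 9.19 TPM.

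Averaged over the 5 stages, 18 of the 49 measured p53 targets were higher in MPNP, as were single stress and interferon-induced genes such as jun and isg15. A few somite and neural progenitor genes were lower by small amounts. Called as sets by camera, the p53 targets, the somite genes and the neural progenitor genes did not pass with an estimated correlation (camera adjusted p = 0.18, 0.092 and 0.27). The genes that rose most were gadd45a (ENSDARG00000043581), a growth arrest and DNA damage gene, by 2.86 ± 0.17 on the log2 scale, and ifit8, of an interferon-induced family, by 2.41 ± 0.23. sec14l8 rose by 2.38 ± 0.15, rnf14 (ENSDARG00000078683), a ubiquitin ligase, by 2.23 ± 0.23 and foxo3b by 2.18 ± 0.18. Next came pnp4a, a purine nucleoside phosphorylase unrelated to the pnp background, by 2.08 ± 0.12, and the calpain gene capn2l by 2.07 ± 0.12. They were followed by phlda3, an inhibitor of AKT induced by p53, by 1.98 ± 0.13, phlda2 by 1.92 ± 0.12, rbl2, of the retinoblastoma family, by 1.91 ± 0.15, metrnlb by 1.86 ± 0.16 and the chemokine receptor gene cxcr3 by 1.82 ± 0.18. Their limma adjusted p ran from 7.5e-07 to 6e-05 (10 libraries per pool), and each was higher at 5 of 5 stages. The falls were smaller. pmp22a changed by -1.02 ± 0.14, nlrc3 by -0.96 ± 0.22, the complement factor H-like gene cfhl5 by -0.93 ± 0.09, hemk1 by -0.92 ± 0.10, stmp1 by -0.87 ± 0.17, the dual oxidase gene duox by -0.83 ± 0.11, and the centriole gene poc1a by -0.74 ± 0.18. acot15 (-0.72 ± 0.14), pimr188 (-0.70 ± 0.11), egfl6 (-0.68 ± 0.09), spata4 (-0.67 ± 0.16) and tert (-0.67 ± 0.12), which encodes telomerase reverse transcriptase, completed the 12. Their limma adjusted p ran from 2.9e-05 (cfhl5) to 0.031 (poc1a), again with the same sign at 5 stages.

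In total 782 of 14774 genes were called in the average, 387 higher and 395 lower (limma). With the replicate block the count was 2574, 1034 higher and 1540 lower, and 781 of the 782 were among them in the same direction. Within the libraries numbered 1 alone, the same comparison with stage as a covariate called 146 genes, and within those numbered 2 alone 282. These fits within numbers, and one without 14 and 16 hpf that called 159, were chosen after the data were seen.

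Of the 63 entries on the p53 target list, 49 genes were measured. In the average 18 were higher and the rest did not pass (19 higher and 1 lower when adjusted over the list alone; 22 higher and 1 lower with the replicate block); the count includes the 4 title genes. gadd45a (ENSDARG00000043581), phlda3, tp53inp1 and sesn1 had the smallest p, with tp53inp1 up by 1.56 ± 0.12 and the sestrin gene sesn1 by 1.14 ± 0.09 (limma adjusted p = 5.6e-06 for both). Others that rose, several of them named only after their values were seen, were casp8, the initiator caspase of death receptors, by 1.73, rps27l by 1.23, sesn3 by 0.95, fosl1 by 0.94, bax, which opens the mitochondrial outer membrane, by 0.56, btg1 by 0.35, plk3 by 0.26 and bcl2l1, an inhibitor of apoptosis, by 0.18. Members picked after their values were seen, such as ddb2 (-0.12), xpc (0.03), perp (-0.05), apaf1 (0.09) and rrm2b (-0.02) stayed close to 0, with limma adjusted p from 0.55 to 0.98. So did the other measured entry of gadd45a (ENSDARG00000104571, -0.07, limma adjusted p = 0.90). As a set the list was higher (camera adjusted p = 1.1e-11), a call lost with an estimated correlation (camera adjusted p = 0.18). The median member differed by 0.09 and the mean by 0.42, since part of the list carried the change.

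**Figure D3:**
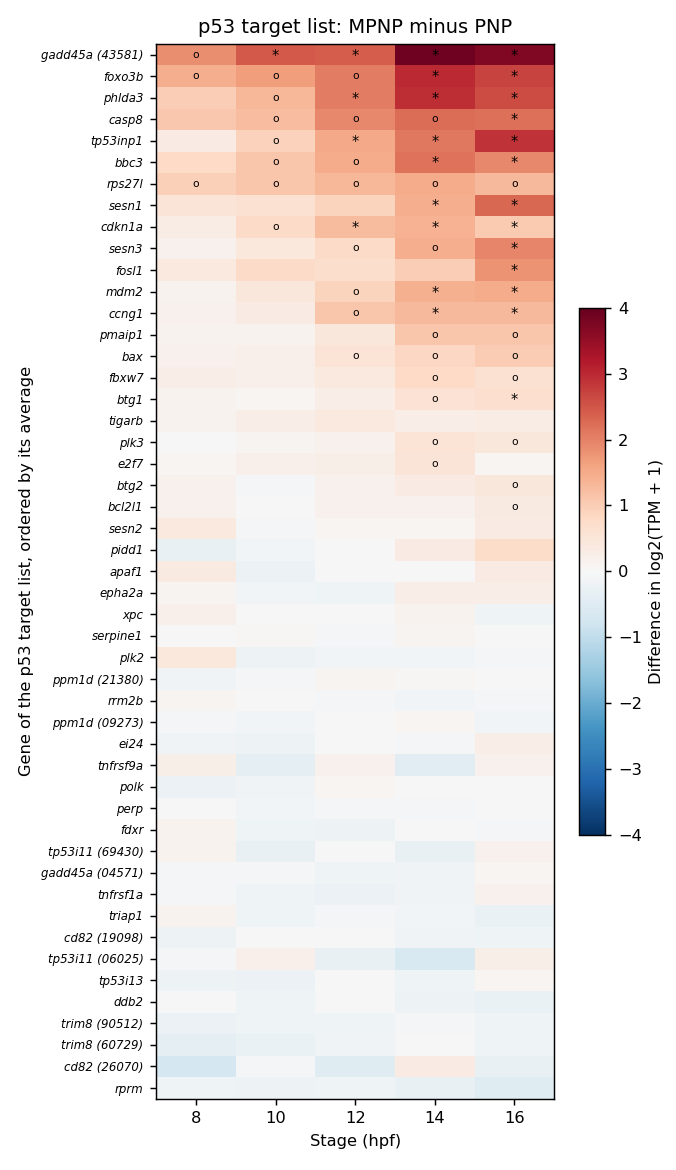
Difference in log2(TPM + 1) between MPNP and PNP (colour) for the 49 measured genes of the p53 target list (y axis, ordered by their average) at each stage in hpf (x axis). Stars mark a limma adjusted p past the 0.05 threshold without the replicate block, and circles one past it only with the block. The top gene, gadd45a (ENSDARG00000043581), goes from 1.87 at 8 hpf to 3.71 at 16 hpf, and the marks become denser with stage, 0 stars at 8 hpf and 13 at 16 hpf.

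Other lists had fewer called members. Of 31 stress and immediate early genes 3 rose: jun by 0.66 ± 0.06, hmox1, a heme oxygenase, by 1.04 ± 0.13 and atf3 by 0.51 ± 0.11 (5 adjusted over the list alone, and 7 higher and 2 lower with the replicate block; camera adjusted p = 0.0014, and 0.039 with an estimated correlation, or 0.2 with the block as well). In the innate immunity list isg15, an interferon-induced ubiquitin-like protein, was the 1 of 8 measured genes that passed (1.61 ± 0.11, limma adjusted p = 1.9e-06; camera adjusted p = 0.036, 0.19 with an estimated correlation, and 0.071 with the developmental offset removed). Of 42 neural progenitor genes 3 fell: sox1 (ENSDARG00000008131) by -0.37 ± 0.07, pax6 (ENSDARG00000103379) by -0.43 ± 0.10 and sox1 (ENSDARG00000069866) by -0.36 ± 0.09 (13 with the block; camera adjusted p = 0.00062, and 0.27 with an estimated correlation). Of 37 somite and muscle genes 4 fell: meox1 by -0.30 ± 0.06, foxc1b by -0.30 ± 0.06, aldh1a2 by -0.22 ± 0.05 and myl10 by -0.33 ± 0.08 (14 with the block; camera adjusted p = 0.00077, and 0.092 with an estimated correlation). Of 16 heart, kidney and lateral plate genes 2 fell, among them foxf2a by -0.28 ± 0.07 (6 with the block; camera adjusted p = 0.0033, and 0.092 with an estimated correlation). Camera also passed neurogenesis (lower, 0.01), tailbud and notochord (lower, 0.031), ribosome biogenesis (higher, 0.031), maternal transcripts (higher, 0.031) and mitochondrially encoded genes (higher, 0.018), with adjusted p of 0.27, 0.19, 0.6, 0.19 and 0.5 with an estimated correlation. With the block 5 neurogenesis genes fell. So did 9 tailbud and notochord genes, while 1 rose, and 5 ribosome biogenesis genes rose. Removing the developmental offset ended the calls for ribosome biogenesis (camera adjusted p = 0.087) and maternal transcripts (0.38, with the median going from 0.08 to 0.00). The remaining lists did not pass: apoptosis machinery (0.065), DNA repair, G1/S and replication, neural crest, and blood and endothelium (0.069 each, but 0.033 with the block and 0.022 with the offset removed for G1/S and replication), endoderm (0.076, but 0.017 with the offset removed), primordial germ cells (0.11), G2/M and mitosis (0.13, but 0.03 with the offset removed), yolk syncytial layer (0.72), epidermis (0.81) and hatching gland (0.95).

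At 8 hpf, in late gastrulation, 46 genes were called between the pools without the replicate block and 579 with it. Of these, 0 and 3 were p53 targets. Higher in MPNP were capn2l (6.21 ± 0.95 against 0.475 ± 0.40 TPM, SD, n = 2), the chaperone gene hsp90aa1 (45.6 ± 14 against 8.32 ± 1.3 TPM). Also higher were the connexin gene gjc4a.1 (log2 difference 1.66 ± 0.27), and the histone genes h2ax2 (1.63 ± 0.29) and h1l1 (1.23 ± 0.19). The small nucleolar RNA snora73 (ENSDARG00000082242) was at 34.1 ± 20 TPM in MPNP and listed at 0 in both PNP libraries. Lower were pimr188 (-1.41 ± 0.24) and rasd1 (31.2 ± 0.39 against 63.2 ± 6.5 TPM). So were slc17a7 (ENSDARG00000016480, -0.95 ± 0.14), the cryptochrome gene cry5 (-0.87 ± 0.13), rorca (-0.87 ± 0.16) and znf1088 (-0.71 ± 0.12). Their limma adjusted p ran from 0.00059 (rasd1) to 0.042 (snora73). In the stress list jun rose, from 9.76 ± 1.9 to 17.3 ± 0.99 TPM (limma adjusted p = 0.038), while hsp70.3 was at 88.7 ± 30 against 6.74 ± 0.51 TPM (limma adjusted p = 0.051, and 0.0061 with the replicate block). The list passed camera (adjusted p = 0.0022, and 0.036 with an estimated correlation, or 0.45 with the block as well). Of the p53 targets 0 passed limma's test, 8 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. With the block 3 passed, foxo3b (limma adjusted p = 0.036), gadd45a (ENSDARG00000043581, 0.016) and rps27l (0.019, named for this count). The list passed camera (adjusted p = 0.0087) but not with an estimated correlation (camera adjusted p = 0.75). G1/S and replication and ribosome biogenesis (camera adjusted p = 0.053 each) passed camera with the block as higher in MPNP (0.02 and 0.0035).

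At this stage 27 genes were higher and 19 lower in MPNP (limma), against 271 and 308 with the replicate block. A fit to the 4 libraries of the stage alone called 0 genes (limma, 876 at an unadjusted p under 0.05), and the total was 15 without the MPNP library numbered 2, 21 without the PNP library numbered 1 and 8 without the PNP library numbered 2.

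At 10 hpf, at the end of gastrulation, 1 p53 target passed without the replicate block and 8 with it. Without the block 11 genes were lower in MPNP, ror2 and hoxa9a among them. gadd45a (ENSDARG00000043581) was at 14.6 ± 8.3 TPM in MPNP and 1.65 ± 0.15 TPM in PNP (limma adjusted p = 0.02). The other leading genes were sec14l8 (log2 difference 2.56 ± 0.33), capn2l (2.11 ± 0.26), b2m, the light chain of class I histocompatibility molecules (1.96 ± 0.35), pnp4a (1.86 ± 0.26) and gjc4a.1 (1.85 ± 0.27). Lower were ror2, a receptor tyrosine kinase for Wnt ligands (5.88 ± 0.092 against 17.6 ± 3.9 TPM), hoxa9a (-1.32 ± 0.19), tbc1d8 (-0.96 ± 0.14), kng1 (-0.91 ± 0.14), nt5c2l1 (-0.81 ± 0.12) and cry5 (-0.80 ± 0.13). Their limma adjusted p ran from 0.0012 (ror2) to 0.048 (b2m). On the p53 list 1 member passed (5 adjusted over the list alone), and 8 with the block, among them cdkn1a (0.77 ± 0.21; limma adjusted p = 0.22 without and 0.038 with the block), foxo3b (1.67 ± 0.41; 0.15 and 0.027) and phlda3 (1.33 ± 0.30; 0.11 and 0.033). Camera passed the list (adjusted p = 0.00013, and 0.6 with an estimated correlation). The maternal transcript org rose, from 14.4 ± 0.30 to 27.9 ± 2.0 TPM (limma adjusted p = 0.041). The maternal list passed camera (adjusted p = 0.00013, median 0.14), but not with an estimated correlation (camera adjusted p = 0.095), and its median was -0.06 once the developmental offset was removed. Mitochondrially encoded genes also passed camera (adjusted p = 0.00013), but not with an estimated correlation (camera adjusted p = 0.6), and their single members did not pass, mt-cyb being at 1.88e+03 ± 127 against 1.29e+03 ± 510 TPM (limma adjusted p = 0.61).

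Here 19 genes were higher and 11 lower (limma), against 145 and 299 with the replicate block. MPNP pools of this stage lay 0.38 h behind PNP along the stage slope, and with that offset removed 13 genes were higher and 8 lower. The mean gap was also 0.38 h at 12 hpf, but there the MPNP libraries differed. Their offsets from the stage mean were -0.02 and -0.36 h for numbers 1 and 2, against -0.20 and -0.18 h at 10 hpf. The total was 5 and 8 without MPNP libraries 1 and 2, and 8 and 6 without PNP libraries 1 and 2, and the p53 target count was 0 without any of these but MPNP library 1 (limma, 10 at an unadjusted p under 0.05 in all libraries).

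At 12 hpf, during early somite formation, 4 p53 targets passed without the replicate block, and 9 genes were lower in MPNP (90 with the block). cdkn1a was at 8.89 ± 2.0 against 3.14 ± 1.1 TPM, phlda3 at 80.9 ± 13 against 18.8 ± 2.9 TPM, tp53inp1 at 29.5 ± 6.4 against 9.57 ± 0.092 TPM and gadd45a (ENSDARG00000043581) at 29.2 ± 7.0 against 4.64 ± 0.88 TPM (SD, n = 2), with limma adjusted p of 0.031, 0.012, 0.039 and 0.019. These were the 4 p53 list members that passed (11 adjusted over the list alone). With the block 12 passed, among them mdm2 (limma adjusted p = 0.016), ccng1 (0.0018), foxo3b (0.015), bbc3 (0.018) and casp8 (0.01). Camera gave an adjusted p of 3.4e-09, and 0.17 with an estimated correlation. The other leading rises were sec14l8 (2.97 ± 0.33), ifit8 (2.83 ± 0.51), pnp4a (2.75 ± 0.26), metrnlb (2.31 ± 0.37) and capn2l (2.18 ± 0.26), with limma adjusted p from 0.00075 to 0.042. Named falls were pcolce2 (ENSDARG00000055575), an enhancer of procollagen processing, by -1.19 ± 0.16, mgst3 by -0.82 ± 0.12 and rasd1 by -0.51 ± 0.10, with limma adjusted p from 0.01 to 0.0498. The heart, kidney and lateral plate list was lower as a set (median -0.35 over 16 genes; camera adjusted p = 2.8e-06, and 0.029 with an estimated correlation, but 0.15 with an estimated correlation and the block). Among its leading members, tbx20 at 0.93 ± 0.69 against 2.05 ± 0.13 TPM and hey2 at 1.09 ± 0.33 against 2.15 ± 0.078 TPM did not pass singly (limma adjusted p = 0.19 and 0.21), though 4 members passed when adjusted over the list alone. Camera also passed neurogenesis (median -0.30, adjusted p = 4.7e-05, and 0.17 with an estimated correlation), neural progenitors (-0.16, 0.00011, and 0.21 with an estimated correlation) and somite and muscle genes (-0.21, 0.00064, and 0.13 with an estimated correlation). With the developmental offset removed the medians were -0.20 for neurogenesis, -0.09 for neural progenitors, -0.21 for somite and muscle genes and -0.27 for the heart, kidney and lateral plate list (camera adjusted p = 0.0026, 0.019, 0.0036 and 0.00034). Camera also passed ribosome biogenesis (adjusted p = 0.0018), maternal transcripts (0.033), stress genes (0.042) and apoptosis machinery (0.045) as higher, and tailbud and notochord (0.015), endoderm and neural crest (0.032 each) as lower. With an estimated correlation these had camera adjusted p from 0.17 to 0.48, but with the offset removed as well tailbud and notochord (0.041) and endoderm (0.028) passed. At the preset correlation, removing the offset ended the calls for apoptosis machinery (0.094), neural crest (0.075) and maternal transcripts (0.81). The block ended those for stress genes, neural crest (0.064 each) and maternal transcripts (0.058). In the somite and muscle list 3 genes fell with the block, among them meox1 (-0.56 ± 0.12, limma adjusted p = 0.035) and acta1 (ENSDARG00000036371, -1.31 ± 0.31, 0.015).

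At 12 hpf 34 genes were higher and 9 lower (limma), against 114 and 90 with the replicate block. The total was 2 without MPNP library 2, and 8 and 5 without PNP libraries 1 and 2, with 0 p53 targets in each case (limma, 12 at an unadjusted p under 0.05 in all libraries). A fit to the 4 libraries alone called 0 (limma, 621 at an unadjusted p under 0.05).

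At 14 hpf 9 of the 49 p53 targets passed and most called genes were higher in MPNP. gadd45a (ENSDARG00000043581) was at 57.5 ± 12 against 3.02 ± 1.1 TPM, foxo3b at 57.6 ± 21 against 6.21 ± 0.59 TPM and phlda3 at 127 ± 26 against 15.6 ± 3.2 TPM (SD, n = 2; limma adjusted p = 0.00037, 0.0028 and 0.00037). mdm2 was at 236 ± 70 against 86.0 ± 0.30 TPM (limma adjusted p = 0.011), and bbc3 and cdkn1a differed by 2.17 ± 0.35 (0.0095) and 1.39 ± 0.21 (0.0069). Of the 49 p53 targets 9 rose (17 adjusted over the list alone) and 18 with the block, fbxw7 among the latter (0.78 ± 0.25; limma adjusted p = 0.33 without and 0.0043 with the block). Camera passed the list (adjusted p = 9.1e-12), but not with an estimated correlation (camera adjusted p = 0.19). Other leading rises were rnf14 (ENSDARG00000078683, 3.05 ± 0.52), metrnlb (3.04 ± 0.37) and rbl2 (2.85 ± 0.34), with limma adjusted p from 0.0013 to 0.012. In the innate immunity list isg15 was at 6.79 ± 2.1 against 0.53 ± 0.23 TPM (limma adjusted p = 0.00053), and in the stress list jun at 30.6 ± 2.6 against 16.2 ± 1.3 TPM (0.0083). Lower were egfl6 (-1.24 ± 0.20), pcolce2 (ENSDARG00000055575, -0.98 ± 0.16), twist1b, a neural crest and mesoderm transcription factor (3.26 ± 0.65 against 7.13 ± 0.74 TPM), col7a1l (ENSDARG00000069692, -0.90 ± 0.14), znf1109 (-0.82 ± 0.16) and gfi1aa, a regulator of primitive blood (4.00 ± 0.028 against 7.33 ± 0.40 TPM), with limma adjusted p from 0.0082 to 0.03. twist1b and gfi1aa were the single members that passed in the neural crest list (21 genes, median -0.15, camera adjusted p = 0.015, and 0.19 with an estimated correlation) and in the blood and endothelium list (22 genes, median -0.14, camera adjusted p = 0.0053, and 0.099 with an estimated correlation). Camera also passed neurogenesis (adjusted p = 0.0027), somite and muscle genes (0.022, but 0.053 with the offset removed), neural progenitors and G1/S and replication (0.035 each) as lower, and stress genes (0.027, but 0.066 with the block) as higher. Ribosome biogenesis passed as higher with the block alone (0.11 without and 0.0097 with it). With an estimated correlation these had camera adjusted p from 0.12 to 0.85.

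At 14 hpf 89 genes were higher and 12 lower (limma), against 210 and 53 with the replicate block. The total was 29 without MPNP library 2 (3 p53 targets), and 53 and 46 without PNP libraries 1 and 2 (5 p53 targets without PNP library 2). A fit to the 4 libraries alone called 0 (limma, 563 at an unadjusted p under 0.05).

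At 16 hpf more genes were called than at the other stages without the replicate block (205), though not with it (516, against 579 at 8 hpf), and 13 p53 targets were among the 205. cdkn2a/b, an inhibitor of cyclin-dependent kinases, was at 15.9 ± 3.8 TPM in MPNP and listed at 0 in both PNP libraries (limma adjusted p = 5.2e-05). gadd45a (ENSDARG00000043581) was at 70.4 ± 10 against 4.67 ± 2.4 TPM, ace, which encodes angiotensin-converting enzyme, at 31.0 ± 5.6 against 2.27 ± 0.16 TPM, rpz5 at 31.7 ± 1.3 against 2.73 ± 0.40 TPM and cxcr3 at 9.04 ± 0.35 against 0.265 ± 0.15 TPM (SD, n = 2), and phlda2 differed by 3.22 ± 0.27 (limma adjusted p from 1.7e-05 to 0.0015). Of the 49 p53 targets 13 rose (18 adjusted over the list alone, 20 with the block), among them sesn1 at 60.6 ± 12 against 11.4 ± 1.4 TPM, tp53inp1 at 95.5 ± 12 against 12.1 ± 2.0 TPM and phlda3 at 128 ± 3.0 against 20.1 ± 2.1 TPM (limma adjusted p = 5.2e-05, 8e-05 and 0.00035). fbxw7 (0.60 ± 0.25; limma adjusted p = 0.62 without and 0.01 with the block) and pmaip1 (11.8 ± 7.8 against 4.61 ± 2.1 TPM; 1 and 0.028) passed with the block alone. Camera passed the p53 list (adjusted p = 1.1e-14), but not with an estimated correlation (camera adjusted p = 0.14).

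The G1/S and replication list was lower as a set at 16 hpf (median -0.21 over 51 genes; camera adjusted p = 2.9e-11), though not with an estimated correlation (camera adjusted p = 0.068). With the block 11 of its members fell, among them the replicative helicase genes mcm5 (170 ± 4.1 against 219 ± 6.2 TPM; limma adjusted p = 0.0076), mcm6 (ENSDARG00000057683, -0.38 ± 0.10; 0.0031), mcm3 (-0.39 ± 0.11; 0.0045) and mcm2 (-0.41 ± 0.12; 0.0097). Without the block these had limma adjusted p of 0.085, 0.11, 0.14 and 0.25. The G2/M and mitosis list was also lower (median -0.13 over 41 genes; camera adjusted p = 0.0018, and 0.36 with an estimated correlation), but its 1 member that passed was ect2, a guanine exchange factor of cytokinesis, and it was higher (26.4 ± 0.93 against 12.9 ± 0.78 TPM; limma adjusted p = 0.018). In the apoptosis list casp8 rose, at 41.8 ± 13 against 8.25 ± 1.7 TPM (limma adjusted p = 0.046), and bax at 106 ± 15 against 51.6 ± 9.3 TPM passed with the block (0.14 without and 0.00026 with it). The annexin gene anxa1 (0.74 ± 0.17; limma adjusted p = 0.046) and isg15 (7.26 ± 0.0071 against 0.77 ± 0.59 TPM; 0.00025) were higher too. Lower were egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors (-1.83 ± 0.35), epd (-1.34 ± 0.30), jam2a, a junctional adhesion molecule (8.78 ± 0.33 against 23.9 ± 6.1 TPM), cfhl5 (-0.91 ± 0.20), ccdc97 (-0.71 ± 0.15) and aldh1a2, the retinoic acid synthesising enzyme of somites (14.9 ± 0.71 against 22.0 ± 0.85 TPM), with limma adjusted p from 0.0042 to 0.048. aldh1a2 was the 1 of 37 somite and muscle genes that fell (camera adjusted p = 0.0016, and 0.14 with an estimated correlation). Camera also passed neural progenitors (adjusted p = 0.0018), DNA repair (0.0024), neurogenesis (0.013) and ribosome biogenesis (0.045, but 0.089 with the offset removed) as lower, and apoptosis machinery (0.021) as higher. With an estimated correlation these had camera adjusted p from 0.32 to 0.56. With the offset removed blood and endothelium (0.025) and heart, kidney and lateral plate (0.014) passed as lower too, and innate immunity (0.04) as higher (camera adjusted p = 0.066 each without).

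At 16 hpf 191 genes were higher and 14 lower (limma), against 379 and 137 with the replicate block. A fit to the 4 libraries alone called 61 genes. The total was 94 and 136 without MPNP libraries 1 and 2 (6 and 7 p53 targets), and 100 and 105 without PNP libraries 1 and 2 (5 and 6 p53 targets).

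**Figure D4:**
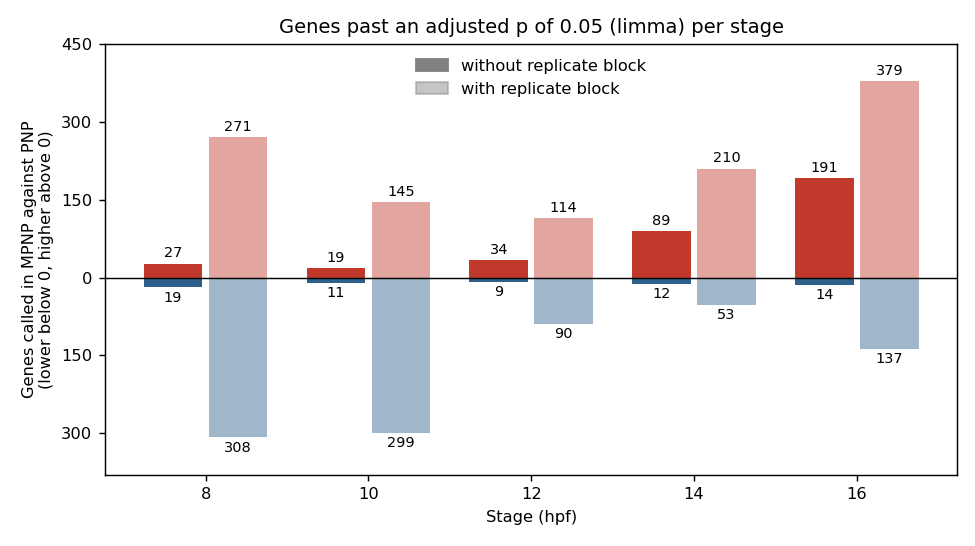
Number of genes called higher (above 0) or lower (below 0) in MPNP than in PNP (y axis) at each stage in hpf (x axis), by limma at an adjusted p of 0.05, without (dark) and with (pale) the replicate block. Without the block higher calls go from 27 at 8 hpf to 191 at 16 hpf; with it lower calls go from 308 at 8 hpf to 53 at 14 hpf and 137 at 16 hpf.

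Whether the difference between pools changed over the stages was tested directly, since the design text asks about the dynamics of target induction. The genes with the clearest change over time all differed more at 16 hpf than at 8 hpf. They were trim63b, a ubiquitin ligase (16 hpf minus 8 hpf 2.28 ± 0.24 on the log2 scale), nupr1a, a stress-responsive gene (1.60 ± 0.19), nim1ka (2.67 ± 0.29), dtex3lb.1 (2.12 ± 0.25), ace (2.60 ± 0.33) and cdkn2a/b (4.06 ± 0.50), with limma F-test adjusted p from 0.0078 to 0.021. ptgs2 (ENSDARG00000004539), which encodes an inducible cyclooxygenase (0.74 ± 0.17), shisa8b (2.16 ± 0.28), the peroxiredoxin gene prdx1 (ENSDARG00000058734, 0.71 ± 0.19) and rasl11b (0.96 ± 0.17) followed with limma F-test adjusted p of 0.036 and 0.037. 15 genes passed the F test (730 at an unadjusted p under 0.05), and 71 with the replicate block. For the single difference of 16 hpf and 8 hpf, 29 genes grew in the direction of MPNP and 4 in that of PNP (limma), against 173 and 91 with the block. Of the p53 targets 2 passed this difference (9 adjusted over the list alone) and 7 with the block. Camera gave an adjusted p of 2.3e-05, and 0.57 with an estimated correlation. The G1/S and replication list moved toward PNP (median -0.30; camera adjusted p = 7.2e-11, and 0.13 with an estimated correlation; 6 members passed with the block). These counts were sensitive to the scale, with 0 genes passing the F test at a pseudocount of 0.1 (limma, 697 at an unadjusted p under 0.05) and 63 at a pseudocount of 5. They also moved with single libraries: the F test passed 1 gene without any one of the 4 libraries of 16 hpf, 9 without MPNP 8 hpf library 2, 2 and 7 without PNP 8 hpf libraries 1 and 2, and 7 without either PNP 10 hpf library. It passed 9 without either MPNP 12 hpf library, 6 without either PNP 12 hpf library, 8 without MPNP 14 hpf library 2, and 5 and 9 without PNP 14 hpf libraries 1 and 2. The 16 hpf minus 8 hpf difference passed 11 and 17 without MPNP 8 hpf libraries 1 and 2, 11 without PNP 8 hpf library 1, 18 without either PNP 10 hpf library, 8 and 16 without MPNP 16 hpf libraries 1 and 2, and 15 and 6 without PNP 16 hpf libraries 1 and 2.

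Development itself changed far more genes than the pool type did. In PNP between 8 and 16 hpf, hatching enzyme and muscle genes were among the largest rises, and pou5f3 and sox32 among the largest falls. The hatching enzyme genes he1.1 and he1.2 reached 633 ± 75 and 175 ± 0.90 TPM at 16 hpf, from 0.41 ± 0.35 and 0.075 ± 0.11 TPM (SD, n = 2). The apolipoprotein gene apoa4b.1 reached 406 ± 17 TPM, the parvalbumin gene pvalb9 447 ± 89 TPM, the skeletal actin gene acta1 (ENSDARG00000036371) 185 ± 27 TPM and the matrix gene emilin3a 329 ± 69 TPM. The pluripotency factor gene pou5f3 went from 842 ± 45 to 4.21 ± 0.37 TPM, the endoderm factor gene sox32 from 138 ± 22 to 0.105 ± 0.021 TPM. nnr went from 375 ± 22 to 1.72 ± 1.3 TPM, alox5b.3 from 534 ± 61 to 4.92 ± 2.4 TPM and add3 (ENSDARG00000056250) from 257 ± 14 to 2.43 ± 0.44 TPM. The spliceosomal RNA u2 (ENSDARG00000113972) was at 138 ± 76 TPM at 8 hpf and listed at 0 in both libraries at 16 hpf. The limma adjusted p of these genes ran from 8.6e-12 to 0.0011 (u2).

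Of 21 maternal transcripts 19 fell, with a median of -2.40 (20 adjusted over the list alone; camera adjusted p = 5.2e-09, and 0.0063 with an estimated correlation). The same holds for 10 of 13 primordial germ cell genes, led by ddx4 at 1.95 ± 0.21 TPM from 80.9 ± 13 TPM (camera adjusted p = 0.00075, and 0.083 with an estimated correlation), and 12 of 16 endoderm genes (camera adjusted p = 0.00075, and 0.1 with an estimated correlation). Of the G2/M and mitosis list 21 of 41 fell and 3 rose (camera adjusted p = 0.00075, and 0.34 with an estimated correlation). Rises prevailed among neural progenitor genes (27 of 42), neurogenesis genes (17 of 21), somite and muscle genes (24 of 37), heart, kidney and lateral plate genes (13 of 16) and yolk syncytial layer genes (16 of 24), with camera adjusted p of 0.00075, 0.00069, 0.02, 0.0086 and 0.017, and of 0.34, 0.2, 0.23, 0.14 and 0.14 with an estimated correlation. Examples are meox1 (95.2 ± 4.0 from 1.03 ± 0.13 TPM), neurog1 (30.8 ± 0.099 from 0.49 ± 0.41 TPM) and pax8 (15.6 ± 1.4 from 0.31 ± 0.14 TPM). In PNP the engineered loci did not pass between these stages without a block (cdkn1a 0.50 ± 0.21, limma adjusted p = 0.058, but 0.043 with the replicate number as a block over all stages and 0.041 without either PNP 12 hpf library; mdm2 -0.06 ± 0.24, 0.84). In total 5572 genes rose and 3934 fell (limma), against 6487 and 4997 with the replicate number as a block over all stages. Median-ratio scaling and quantile normalization moved the median of all genes from 0.17 to 0.03 and -0.04 and gave 4561 rising and 4863 falling genes under quantile normalization, so the balance of rises and falls depends on the scaling.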

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

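The direct test of a change over the stages was planned, while the test of the genes called at 12 hpf with the replicate block, the ratio of the 16 to the 10 hpf difference, the correlation with the stage slope at 8 hpf, the splits for the F test and the share of a difference left without the offset were chosen after the result was seen, as was the reading of the bound for a loss in 25% of the embryos. The bootstrap intervals in this part resampled genes with the libraries held fixed, so they hold no spread between samples.

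Of the 15 genes whose difference between MPNP and PNP itself differed between the stages by limma's F test, 10 are described here (adjusted p from 0.0078 to 0.037, n = 2 libraries per group), and each is given as the 16 hpf difference minus the 8 hpf difference on the log2 scale. trim63b had 2.28 and nim1ka 2.67. nupr1a had 1.60 and dtex3lb.1 2.12. ace had 2.60 and cdkn2a/b 4.06, the latter listed at 0 in PNP at 16 hpf. ptgs2 (ENSDARG00000004539) had 0.74 and prdx1 (ENSDARG00000058734) 0.71. shisa8b had 2.16 and rasl11b 0.96. At a pseudocount of 0.1 the test passed 0 genes (limma, 697 at an unadjusted p under 0.05), and leaving out any one of the 4 libraries of 16 hpf left 1. Of 100 splits of the 4 libraries of each stage, 15 passed as many genes in the F test (15 genes in the real one, at most 1375 in the others). With the replicate block 3 of the 13 splits that part every pair passed as many (71 genes in the real one, at most 262 in the others). A split that swaps pools or numbers at some stages turns a constant difference into a change over the stages. The splits therefore cannot tell chance from such a change, and chance is not excluded for either count. The largest counts point to a structure of the samples.

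The first pattern weighed is the set of genes that were higher in MPNP by more at later stages. Of 100 splits of the 4 libraries of each stage, only the real one called as many genes in the average (782 genes against at most 358 in the others). With the replicate block it called 2574 against at most 1 among the 13 splits that part every pair, too few splits for a verdict alone. So chance is argued against for the count in the average, which takes higher and lower genes together. The count says nothing of the growth over the stages. A split by replicate number called 6939, which points to a structure of the samples. A difference in developmental age is argued against for most calls at 14 hpf, where removing the offset ended 7.92% of them. At 16 hpf it ended 7.32%, but the slope used there was taken between 12 and 14 hpf, so that result is weaker. At both stages the differences followed the stage slope weakly with the sign of the offset (r = -0.25 and 0.28). Age is also argued against as the whole cause at 10 and 12 hpf, where the removal left 94.1% and 97.9% of the median difference (95% bootstrap intervals 79.1 to 108% and 93.5 to 110%). The removal ended 36.7% and 14.0% of the calls there, whose median difference went from 1.21 to 0.83 (SE 0.19 and 0.17) and from 1.00 to 0.78 (SE 0.18 before and after), so age stays open for these (r = -0.40 and -0.008 over all calls). The 114 genes called higher at 12 hpf with the block had a median difference that grew by 0.75 between 8 and 16 hpf (95% bootstrap interval over genes 0.34 to 0.97). This met the terms set against a fixed difference between the families of parents. The interval holds no spread between the libraries of a group, so it does not decide the question for the pools. The 387 genes higher in the average grew by 0.50 (0.40 to 0.65), and the 18 p53 targets among them by 1.12 (0.65 to 1.48). The 49 p53 targets as a whole gave 0.18, with an interval that includes 0 (-0.0094 to 0.44). There each gene was signed by the direction of its own average, so this value is not a growth toward MPNP. Without that sign the median 16 minus 8 hpf difference of the 49 was 0.25, with no interval calculated. That p53 activity built up in mutant embryos stays a hypothesis, since the embryos of a pool were not genotyped one by one.

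The second pattern is the set of 395 genes lower in MPNP in the average. If each fell in the mdm2 mutant embryos alone and these made up 25% of the pool, no pooled fold could lie below 0.75; of the 395, 29 (7.34%) had a 95% interval below it, which passed the bound of 5% set in advance. That bound was wrong, as was decided after the value was seen: the genes were chosen for low values, so their intervals lie low, 1 gene passed a test against 0.75 adjusted by Benjamini-Hochberg (2 with the block), and the share of mutants in a pool is unknown. At 8, 10, 12, 14 and 16 hpf the interval lay below 0.75 for 14 of 19, 11 of 11, 8 of 9, 11 of 12 and 9 of 14 lower genes. The same choice of low values bears on these, and 0 genes passed the adjusted test at any of these stages (limma, 58, 90, 75, 34 and 24 at an unadjusted p under 0.05), while with the block 1 passed at 8 hpf and 1 at 12 hpf. The median difference of these genes was no larger at 16 than at 8 hpf (change in size -0.057, interval -0.10 to -0.03), which is consistent with a difference between the families of parents, while the 90 genes called lower at 12 hpf with the block gave 0.018 (-0.06 to 0.09) and decided nothing. Removing the developmental offset left 91.3% of the median difference (interval 87.6 to 94.2%, median -0.36 before and -0.33 after). This argues against a delay along the stage slopes as the whole cause. The slopes at 8 and 16 hpf came from other stages, so the removal tests a delay less well there. The removal ended 30.9% of the calls, whose median size went from 0.31 to 0.24 (SE 0.07 before and after). Loss in mutants and parental background stay open, and a fall in heterozygous embryos was not tested.

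The third pattern is the set of 46 genes called at 8 hpf. The differences did not follow the stage slope (r = -0.084). The slope used at 8 hpf came from other stages, so the correlation does not test change around 8 hpf, and age stays open. The share of calls ended (2.17%) was set aside because the offset at this stage was too small (-0.02 h) for its removal to test age. That offset rests on the same slope, so its small size does not decide the question either. The ratio of the 16 to the 10 hpf difference over all 46 (0.27, interval over genes 0.08 to 0.49) met the terms set against a lasting difference between families. The intervals of the higher genes alone (0.18, -0.02 to 0.93) and of the lower alone (0.39, 0.09 to 0.62) reached above 0.5. These intervals hold no spread between the libraries of a group, so the ratio does not decide the question. The ratio of the 16 to the 8 hpf difference (0.14) decides nothing, since the genes were chosen at 8 hpf. Maternal transcripts that differ between the mothers of the pools are a possible explanation for part of them: 18 of the 46 (39.1%) fell between 8 and 16 hpf in the pool with the lower level, against 24.8% of the other genes tested (Fisher's exact test, unadjusted p = 0.0383, 1 of 18 tests of explanations). Stress at collection or in the mutants, in view of hsp90aa1 and jun, was not tested.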

How the results depend on the processing

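The block over all stages for the pool comparisons, the fits to libraries of 1 number, the average over 8 to 12 hpf and the block without title genes were chosen after the data were seen; the other settings were planned. All counts are of genes called by limma, against 46, 30, 43, 101 and 205 at 8, 10, 12, 14 and 16 hpf, 782 in the average, 33 for 16 minus 8 hpf, 15 in the F test and 0, 1, 4, 9 and 13 p53 targets at the 5 stages (18 in the average). The replicate block within stage gave 579, 444, 204, 263 and 516, then 2574, 264 and 71, and 3, 8, 12, 18 and 20 p53 targets (2, 6, 9 and 14 without title genes at 8 to 14 hpf). It adds a term that takes up the shared deviation of same-numbered libraries. As a block over all stages it gave 649, 437, 275, 294 and 481, then 2378, 275 and 131, and 4, 6, 13, 19 and 20 p53 targets. The calls without the block that it kept in the same direction were 46 of 46, 30 of 30, 40 of 43, 100 of 101 and 202 of 205 at the stages and 781 of 782 in the average. Fitting the 4 libraries of a stage alone gave 0, 0, 0, 0 and 61 (876, 657, 621 and 563 at an unadjusted p under 0.05 in limma for the stages with 0) and 0, 0, 0 and 8 p53 targets from 10 to 16 hpf (7, 11 and 17 at an unadjusted p under 0.05 where 0), since fewer libraries carry the spread. The libraries numbered 1 alone gave 146 in the average (7 p53 targets), those numbered 2 alone 282, and 8 to 12 hpf alone 159 (7 p53 targets), all with fewer samples. A pseudocount of 0.1 gave 6 for 16 minus 8 hpf and 0 in the F test (697 at an unadjusted p under 0.05), and a pseudocount of 5 gave 113 and 63, with 86 at 8 hpf and 0 p53 targets at 10 hpf (9 at an unadjusted p under 0.05). No filter gave 98 at 8 hpf, 375 at 16 hpf, 103 for 16 minus 8 hpf, 59 in the F test and 2 p53 targets at 12 hpf; a mean TPM of at least 5 gave 24, 16, 60 and 106 at 8, 10, 14 and 16 hpf, 493 in the average, 4 for 16 minus 8 hpf and 1 in the F test, with fewer genes tested. Median-ratio scaling gave 77 at 8 hpf and 59 at 10 hpf, with 1 and 2 p53 targets, and quantile normalization gave 24 at 8 hpf, 81 at 12 hpf, 54 for 16 minus 8 hpf and 31 in the F test. For pseudocount, scaling and the absent filter the cause was not tested. Of the lists, 2, 4, 13, 9 and 10 passed camera at the stages, 12 in the average, 7 for 16 minus 8 hpf and 11 in development; with an estimated correlation 1, 0, 1, 1, 0, 2, 0 and 1 passed, with fry 1, 0, 4, 1 and 3 at the stages, 0 for 16 minus 8 hpf and 19 in development, and with the block 5 at 8 hpf. Each single library left out, with the lone one left assumed to vary like the other groups, gave from 8 (without PNP library 2) to 48 at 8 hpf, 5 (without MPNP library 1) to 8 at 10 hpf, 2 (without MPNP library 2) to 54 at 12 hpf, 29 (without MPNP library 2) to 83 at 14 hpf and 94 (without MPNP library 1) to 136 at 16 hpf. The range was 549 to 707 in the average, 6 (without PNP 16 hpf library 2) to 40 for 16 minus 8 hpf and 1 (without any single 16 hpf library) to 21 in the F test, and for p53 targets 0 to 0, 0 to 1, 0 to 4, 3 to 8 and 5 to 7 at the stages and 16 to 18 in the average; the other libraries that moved a count are given with the stages. Development (9506 genes) ran from 6548 to 12184 over all settings. Removing the trend, robust moderation and removing the developmental offset moved none of the counts of called genes, p53 targets or lists passing camera at the preset correlation beyond a ratio of 1.5, but with an estimated correlation and the offset removed 4 lists passed at 12 hpf. Among 3348 alternative values of 153 named results, 0 reversed. A reversal here is a change of sign with a call in at least 1 of the 2 fits compared. Sign changes without a call did occur, 3 of them in development under quantile normalization. Others came in development and at 8, 10 and 12 hpf with 1 library left out. In every setting 12 of 12 in development, 14 of 30 in the average and 7 of 18 at 16 hpf stayed called. Of those at 8, 10, 12 and 14 hpf (12, 12, 10 and 17) 0 did, and 0 of the 10 for the stage difference. For these comparisons limma had 1307, 1309, 959, 927 and 730 genes at an unadjusted p under 0.05. Over 184 pairs of list and comparison, 20 list medians changed sign under median-ratio scaling or quantile normalization, among them the p53 targets in development (0.24, 0.11 and -0.09). Depth is not kept by TPM, so what depth limits is unknown.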

Other observations

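The test for called genes near mdm2 was planned, and the genes described in this part were picked after their values were seen.

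The genes ifit8 (2.41 ± 0.23 on the log2 scale in the average), isg15 (1.61 ± 0.11) and, at 10 hpf, b2m (1.96 ± 0.35) were higher in MPNP. The fixed innate immunity list gave no clear call as a set: isg15 was the 1 of its 8 measured genes that passed, with a median of 0.04 and a camera adjusted p of 0.036, or 0.19 with an estimated correlation. The germ cell gene nanos3 was higher by 0.48 on average (limma adjusted p = 0.015), and the carboxypeptidase gene cpn1 (ENSDARG00000096720) was at 24.6 ± 1.6 against 2.56 TPM at 16 hpf (n = 2, limma adjusted p = 0.024).

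Genes near mdm2 were tested because fish chosen for an mdm2 mutation could carry the surrounding stretch of chromosome from another strain. Of the 90 protein-coding genes of the stretch in the reference order, 50 (55.6%) had a tested gene, below the 80% asked of such a check, so the test decides nothing. The prediction written in advance did not name this limit. Its terms against a difference between families were met, since among these 50, 1 was called in the average (2%, against 5.2% of the tested genes that could be placed). A planned test over whole chromosomes was not run, because only 74.9% of the called genes could be placed. It was to take the genes called at all 5 stages, which were 4 without the replicate block and 23 higher and 7 lower with it.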
